A study of Mus musculus with 12 samples.

How the data were processed

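Total RNA from mouse liver was extracted with TRIzol and made into Illumina sequencing libraries, per the labels' protocols. The deposited table holds raw counts per Ensembl gene for 12 libraries; that the values are counts was read from the table, whose entries are whole numbers and whose column totals differ. Bowtie 0.12.2 and the genome build mm8 are named per the submitters' processing notes. The counting program, its annotation and its treatment of strand and of reads that map to several genes are not given in the sources used here. Reads shared between paralogs, pseudogenes or overlapping genes could thus have been counted in either, and reads of antisense partners cannot be told apart. The table lists 53465 gene IDs, of which 53274 were paired with a symbol by GENCODE M21; the other 191 held at most 0.0379% of a library's counts and kept their ID. Since these IDs belong to a later assembly than mm8, no coordinates are given and the annotation was used for names and for transcript length and GC content. No row lacked a gene, 26261 IDs had 0 counts in all libraries, and all 12 columns were used.

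Libraries were grouped by the genotype and diet in the labels into control on chow, control on HFD, KO on chow and KO on HFD, with 3 libraries each. The genotype is called a hepatocyte-specific knockout in the series description and a knockdown in the samples' genotype label; knockout is used here. Totals ranged from 18215008 to 22378180 counts, a ratio of 1.23. At this depth the self-test described here gives the precision of a call where few genes differ. Intervals and floors cover counting error only. Libraries of a group were compared by chi-square over genes with at least 100 counts in a pair: the median was 1.59 to 2.34 times its expectation in the 12 pairs within groups and 5.43 to 11.0 times in the 54 pairs between groups. All within-group pairs thus differed by more than sampling noise, and each library was counted as 1 replicate.

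Genes were filtered with edgeR 4.0.16 (filterByExpr by group), which left 14778, and scaled by TMM. One quasi-likelihood model (glmQLFit and glmQLFTest, R 4.3.3) of the 4 groups without covariates was fitted to all 12 libraries, which share an estimate of the spread. Contrasts were KO against control on each diet, HFD against chow in each genotype and the diet by genotype interaction. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all tested genes. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM are counts scaled by the TMM-adjusted library size.

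Before the data were examined, 37 gene lists covering lipid, glucose, bile acid and xenobiotic metabolism, sex-biased genes, fibrosis, liver and blood cell types, inflammation, stress, the clock, proliferation, mitochondria and ribosomes were written, along with the comparisons and the other settings to try. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Counts of members are given over all tested genes and adjusted over the list alone. Named genes were set by a rule: Pld1, Pparg and Cd36; in each comparison up to 10 higher and 10 lower genes with the largest fold among those past the threshold with at least 5 CPM in the higher group and no overlap between groups (5 each for the interaction), leaving out names that are only gene models (some named items are not reported here); and up to 4 members with the smallest p of each list past its set test. Some of these genes are also given in comparisons other than the one that named them. A group at 0 counts was set to a floor of 3 counts over the group, and a group with 1 to 3 counts was given as a ratio with an exact binomial 95% interval.

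For the comparison of diet and knockout effects on HFD, which share the 3 control libraries, 100 data sets of unchanged groups were simulated. The model was tested on simulated data for KO against control on HFD with 14778 genes, of which 200 were changed: 36% of 50 genes changed 1.25-fold were recovered, 72% at 1.5-fold, 90% at 2-fold and 94% at 4-fold, and 9 of 14578 unchanged genes were called. With a simulated trend of the fold changes on transcript length, of a size not matched to these data, 6020 of 14578 unchanged genes (41.3%) were called, and 5 after the trend was removed. A simulated list of genes changed 1.25-fold was called and none of 36 unchanged lists was. The simulated genes were drawn independently, so this does not test how often lists of correlated genes are called without a change. Alternatives were no count filter, a filter of 5 CPM in a group mean, DESeq2 1.42.0 size factors, upper quartile scaling, DESeq2's Wald test, limma-voom, fits of the 2 groups compared alone, the replicate number as a block, leaving out each library, and a fold of at least 1.5. A coefficient of variation fixed at 20% or 40% and the removal of each library's trend on transcript length and GC content were added after seeing the data. With the fixed values the likelihood ratio test (glmFit and glmLRT) replaced the quasi-likelihood test. Figures were drawn with matplotlib 3.10.9.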

Results

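Mouse liver RNA was sequenced as 12 libraries in 4 groups of 3. The groups crossed genotype with diet. Control mice carried the floxed Pld1 gene, and the other mice are described as hepatocyte-specific Pld1 knockouts (KO). Both were fed normal chow or a high-fat diet (HFD), given for 20 weeks according to the series description. Pld1 encodes phospholipase D1, which makes phosphatidic acid from phosphatidylcholine. The libraries held 18215008 to 22378180 counts over genes, and 19967 to 20853 genes had at least 1 count in a library. The 10 most abundant genes took 17.9% to 18.6% of the counts and mitochondrially encoded genes 5.98% to 7.50%. The latter share was lower in every KO library than in every control library on the same diet, at 5.98% to 6.16% against 7.17% to 7.28% on chow and 6.49% to 6.76% against 7.24% to 7.50% on HFD. The Y-linked gene Ddx3y had 1229 to 1732 counts per library and Xist 0 to 7. Libraries of a group differed by little. The common biological coefficient of variation was 3.95%, and the median coefficient of variation within groups was 2.52% over the 2762 genes with a depth-scaled count (CPM) of at least 50. The labels do not say that the 3 libraries of a group came from separate animals, and the p-values then measure only the spread between these libraries, which may be technical. Fold sizes and levels are therefore given first. Errors of levels are SD with n = 3, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14778 genes.

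The targeted gene was lower in every KO library than in every control library on the same diet. Pld1 (ENSMUSG00000027695) was at 10.6 ± 1.28 CPM in controls and 4.03 ± 0.614 CPM in KO livers on chow, and at 7.13 ± 0.624 CPM in controls and 2.60 ± 0.575 CPM in KO livers on HFD. KO livers thus held 38.2% of the control level on chow (log2 fold change -1.39, SE 0.14, adjusted p = 1.08e-09) and 36.4% on HFD (-1.45, SE 0.16, adjusted p = 7.54e-09). Whole liver holds other cells than hepatocytes, and counts over the whole gene include any exons outside the deleted part, so the remaining counts do not measure how complete the deletion was. The samples' genotype label calls these livers a knockdown, which the remaining level does not settle. Pld1 was also lower on HFD than on chow, in controls (-0.57, SE 0.13, adjusted p = 0.000615) and in KO livers (-0.62, SE 0.18, adjusted p = 0.00561). Without KO_HFD replicate 2 the latter was -0.45 with adjusted p = 0.0586, the highest of 20 alternatives, whose lowest was 0.00322. The series asks whether less PLD1 lowers hepatic lipid through PPARg and the fatty acid transporter CD36. Pparg (ENSMUSG00000000440), a nuclear receptor that drives lipid storage genes, was at 15.7 ± 0.720 CPM in controls on chow, 19.8 ± 1.05 in controls on HFD, 10.9 ± 1.09 in KO livers on chow and 13.05 ± 0.988 in KO livers on HFD. It was lower in KO livers on HFD (-0.60, SE 0.084, adjusted p = 5.95e-07) and on chow (-0.52, SE 0.089, adjusted p = 1.95e-05). With the diet Pparg rose by 0.34 in controls (adjusted p = 0.00107) and by 0.26 in KO livers (adjusted p = 0.027); the latter was lost without KO_chow replicate 1, KO_HFD replicate 1 or KO_HFD replicate 3 (adjusted p = 0.168, 0.112 and 0.0808, with a range of 0.0135 to 0.168 over 20 alternatives) and with the trend on length and GC removed (0.0588, at a log2 fold change of 0.22). Cd36 (ENSMUSG00000002944) rose from 54.2 ± 0.612 CPM in controls on chow to 226 ± 9.46 on HFD, a 4.16-fold difference, and stood at 102 ± 4.88 CPM in KO livers on HFD, which is 45.2% of the control level (-1.15, SE 0.038, adjusted p = 3.47e-22). On chow, Cd36 was at 49.6 ± 1.95 CPM in KO livers (-0.13, adjusted p = 0.0289). This small difference was lost by DESeq2's Wald test (adjusted p = 0.0566), by limma-voom (0.0697), without control_chow replicate 1, 2 or 3 (0.0509, 0.0907 and 0.0538), without KO_chow replicate 3 (0.154) and with the trend on transcript length and GC content removed (0.311), where the 20 alternatives set beforehand ranged from 0.016 to 0.154. If every gene varied by 20%, a setting chosen after seeing the data, Pparg no longer passed between genotypes on HFD or chow (adjusted p = 0.219 and 0.295), nor did the diet differences of Pld1 in controls and KO livers (0.193 and 0.195) or of Pparg (0.605 and 0.834). At 40% neither Pld1 between genotypes (adjusted p = 0.315 and 0.276) nor Cd36 on HFD (0.844) passed. An exact two-sided permutation test of each of these genes between any 2 of the groups compared gave p = 0.1, the smallest that 3 against 3 libraries allow.

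**Figure D1:**
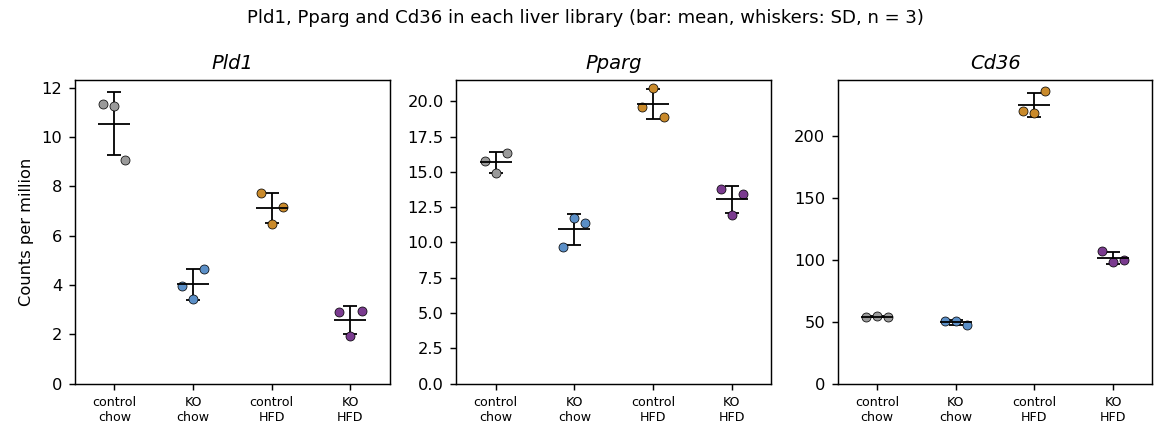
Depth-scaled counts (CPM) of Pld1, Pparg and Cd36 (vertical axes, linear, from 0) in each of the 12 libraries by group; points are libraries, bars the mean of 3 and whiskers the SD. Pld1 lies at 2.60 CPM in KO livers and 7.13 CPM in controls on HFD, and Cd36 at 102 and 226 CPM.

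The HFD comparison in control livers asks what the diet did without the knockout. Most genes of the lists for fatty acid oxidation, lipid droplets, fibrosis and the female pattern of liver expression were higher on HFD, and most of those for the male pattern, the acute phase, neutrophils and erythroid cells were lower. Cidec, a lipid droplet protein, rose from 6.07 ± 0.586 to 61.1 ± 3.94 CPM (log2 fold change 3.33, SE 0.078), and Cyp4a14, a fatty acid hydroxylase induced by PPARa, from 99.6 ± 1.02 to 1221 ± 15.9 CPM (3.62, SE 0.026). The hepatic hormone gene Fgf21 rose by 3.54, the apolipoprotein gene Apoa4 by 3.25 and Rgs16, a regulator of G protein signalling, by 4.07 on the log2 scale. Hsd3b5, a steroid dehydrogenase gene of male mouse liver, was at 130 ± 2.48 CPM on chow and 1.47 ± 0.419 CPM on HFD (-6.48, SE 0.083). Orm2, an acute phase gene, fell by 3.94. Moxd1 had 1126 counts on chow and 1 on HFD over 3 libraries each, a ratio of 1251 with an exact 95% counting interval of 224 to 49440. In all, 5571 of 14778 genes passed the threshold, 2773 higher and 2798 lower, and 1793 of them differed by at least 1.5-fold.

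Among the gene lists fixed before the data were examined, 36 of 38 PPARa targets and fatty acid oxidation genes were higher and 1 was lower in controls on HFD (36 and 1 adjusted over the list alone), with a median log2 fold change of 0.61. Vnn1 rose by 2.32 and Aldh3a2 by 1.52. Of 18 tested PPARg targets and lipid droplet proteins, 16 were higher and 2 lower (16 and 2 adjusted over the list alone), with Plin4 at 2.74 and Plin2 at 0.96; this list holds Pparg and Cd36, named in the series title, and is not independent evidence of its direction. None of the 26 male-biased liver genes was higher and 24 were lower (24 adjusted over the list alone), among them Serpina1e at -3.04, C8b at -2.01 and the urinary protein gene Mup7 at -1.80. Female-biased genes went the other way, with 12 of 15 higher and 1 lower (12 and 1 adjusted over the list alone), led by Cyp2a4 at 4.80, Cyp17a1 at 3.29 and Cyp2b9 at 3.22. Fibrosis and stellate cell markers were higher for 24 of 29 members and lower for 1 (25 and 1 adjusted over the list alone), with Col1a1 at 16.7 ± 0.446 against 4.18 ± 0.367 CPM and Col3a1 at 1.20 on the log2 scale. Cell cycle genes were higher for 18 of 26 members, with none lower (20 adjusted over the list alone), including Cdkn1a, which encodes a cell cycle inhibitor, at 2.03 and Mki67 at 1.36. Sinusoidal endothelial markers were higher for 12 of 20 (12 adjusted over the list alone), Vwf by 1.26, and macrophage markers for 13 of 29, with 2 lower (13 and 2 adjusted over the list alone), without passing the set test (adjusted p = 0.124).

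Acute phase genes were lower for 16 of 25 members and higher for 6 on HFD in controls (16 and 6 adjusted over the list alone), with Saa2 at -2.86 and Saa1 at -2.51. Markers of neutrophils and erythroid cells moved with them. Of 13 neutrophil markers 11 were lower (11 adjusted over the list alone), Ngp by -5.89, and all 8 erythroid markers were lower (8 adjusted over the list alone), Hbb-bs from 38.7 ± 1.49 to 14.5 ± 1.00 CPM. Of 13 T, NK and B cell markers 4 were lower and 1 higher (5 and 1 adjusted over the list alone), and their set test did not pass (adjusted p = 0.247). The 32 cytosolic ribosomal protein genes were all lower (32 adjusted over the list alone), by a median of 0.37 on the log2 scale (median log2 fold change -0.37). The set tests of the lists given so far as higher or lower, other than macrophage and lymphocyte markers, passed with a preset correlation of 0.01 and with an estimated one. Cholesterol synthesis genes were higher for 17 of 25 members and lower for 4 (18 and 4 adjusted over the list alone), Sqle by 0.53, but adjusted p = 0.066 with an estimated correlation. The bile acid list had 14 of 24 members lower and 7 higher (14 and 7 adjusted over the list alone), Cyp7b1 by -1.37, with adjusted p = 0.128 with an estimated correlation.

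The comparison of KO with control livers on HFD is the one the series description names. In KO livers on HFD most genes of the lipid droplet, cell cycle and fibrosis lists and 7 of 15 female-biased genes were lower than in controls, and most male-biased, acute phase, neutrophil, erythroid and ribosomal protein genes were higher. Hsd3b5 was at 28.7 ± 2.04 CPM against 1.47 ± 0.419 (log2 fold change 4.30, SE 0.10), Cyp1a2, a pericentral xenobiotic oxidase, at 1459 ± 9.41 against 341 ± 4.34 CPM (2.10, SE 0.021) and Saa1 at 272 ± 1.28 against 61.4 ± 1.55 CPM (2.15, SE 0.026). Scara5, a ferritin receptor gene, was higher by 3.15, the immunoglobulin gene Ighg2b by 3.42, and the clock genes Ciart and Dbp by 2.29 and 2.04. Among the largest falls were Gprc5b at -2.44, Ly6d at -2.41, Mki67 at -2.35, Gsta1 at -2.29, Cyp2b13 at -2.20 and the lipid droplet gene Cidea at -1.92. Past the threshold were 4784 genes, 2475 higher and 2309 lower. Most of these differences were small, since 1063 genes, 441 higher and 622 lower, differed by at least 1.5-fold and 490 by at least 2-fold. With the variation of every gene set to 20%, a setting chosen after seeing the data, 534 genes passed. Fold changes went with transcript length across 14762 genes (Spearman's rho -0.248, genes not being independent), shorter transcripts being higher in KO livers, and 4387 genes passed with each library's trend on length and GC content removed, 3735 of them among the 4784.

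Of the 18 PPARg targets and lipid droplet proteins, 13 were lower and 2 higher in KO livers on HFD (14 and 2 adjusted over the list alone), with a median of -0.42. Cidec stood at 19.5 ± 0.658 against 61.1 ± 3.94 CPM (-1.65, SE 0.064), Plin4 at 62.2 ± 5.40 against 144 ± 2.97 CPM (-1.21, SE 0.047) and Plin2 at -0.54. The same caution applies to this list as above. PPARa targets and oxidation genes were lower for 25 of 38 members and higher for 6 (26 and 6 adjusted over the list alone), by small amounts: the median was -0.19, with Aldh3a2 at -0.56 and Ehhadh at -0.45. De novo lipogenesis genes went both ways, 10 higher and 11 lower of 25 (10 and 11 adjusted over the list alone), and their set test did not pass (adjusted p = 0.794). The NRF2 and glutathione list had 15 of 25 members lower and 1 higher (16 and 3 adjusted over the list alone), including Gstm3 at -1.54 and Gclc, a subunit of the rate-limiting enzyme of glutathione synthesis, at -0.68. On chow 14 were also lower and 3 higher in KO livers (14 and 4 adjusted over the list alone), with a median of -0.15. The set test passed there too (adjusted p = 1.29e-05, and 0.0151 with an estimated correlation). That of the interaction did not (adjusted p = 0.315), but it passed with the trend on length and GC removed (0.0309).

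Male-biased genes were higher for 21 of 26 members and lower for none (21 adjusted over the list alone), with a median of 0.89; Serpina1e was at 2.18, Slco1a1 at 1.56 and Mup7 at 1.44. Of 15 female-biased genes 7 were lower and 3 higher (9 and 3 adjusted over the list alone), with Cyp2b9 at -1.16 (SE 0.038) and Cyp2a4 at -1.88. In KO livers on chow 7 were also lower and 3 higher (8 and 3 adjusted over the list alone), though the set test did not pass there (adjusted p = 0.103). The median interaction of this list was -0.0035, and its set test did not pass (adjusted p = 0.387). Mup, Serpina1, Cyp2a, Cyp2b, Cyp4a, Saa and globin genes have near-identical paralogs or pseudogenes, and how shared reads were counted is not given in the sources used here, so single members of these families are uncertain. Fibrosis and stellate cell markers were lower for 15 of 29 members and higher for 1 (15 and 1 adjusted over the list alone), Col1a1 at 6.30 ± 1.20 against 16.7 ± 0.446 CPM and Col3a1 at -0.90. Cell cycle genes were lower for 16 of 26 and higher for none (18 adjusted over the list alone), Cdc20 by -3.35 at under 5 CPM in both groups.

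Acute phase genes were higher for 22 of 25 members and lower for 1 (22 and 1 adjusted over the list alone), with Saa2 at 1.85, Orm2 at 1.84 and Hp, which encodes haptoglobin, at 0.84. Neutrophil markers were higher for 9 of 13 members (9 adjusted over the list alone). Lcn2, which is also in the acute phase list, was at 1.76, and Ltf had 51 counts against 3, a ratio of 18.9 with an exact 95% counting interval of 6.13 to 94.9. Mpo had no count in the 3 control libraries on HFD and was at least 11.1-fold higher in KO livers, against a floor of 3 counts over the group. Of 8 erythroid markers 7 were higher and 1 lower (7 and 1 adjusted over the list alone), Hbb-bs at 39.1 ± 3.05 against 14.5 ± 1.00 CPM, and of 29 macrophage markers 14 were higher and 1 lower (15 and 3 adjusted over the list alone), with Marco at 1.38, Cd5l at 0.55 and the Kupffer cell gene Clec4f at 0.50. Ribosomal protein genes were higher for 31 of 32 members (31 adjusted over the list alone), Rpl3 by 0.70. Clock genes were higher for 12 of 21 members and lower for 5 (12 and 5 adjusted over the list alone), and bile acid genes for 15 of 24, with 6 lower (15 and 6 adjusted over the list alone), Cyp7b1 at 1.11 and Cyp8b1 at -0.51. All the set tests of the lists given here as higher or lower passed also with an estimated correlation. Cholesterol synthesis genes were higher for 16 of 25 members and lower for 5 (18 and 5 adjusted over the list alone), Sqle by 0.36, with adjusted p = 0.079 with an estimated correlation. In the xenobiotic list, with 12 of 24 members higher and 10 lower (13 and 10 adjusted over the list alone), the set test and the median of 0.16 pointed up and the mean of -0.04 pointed down.

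**Figure D2:**
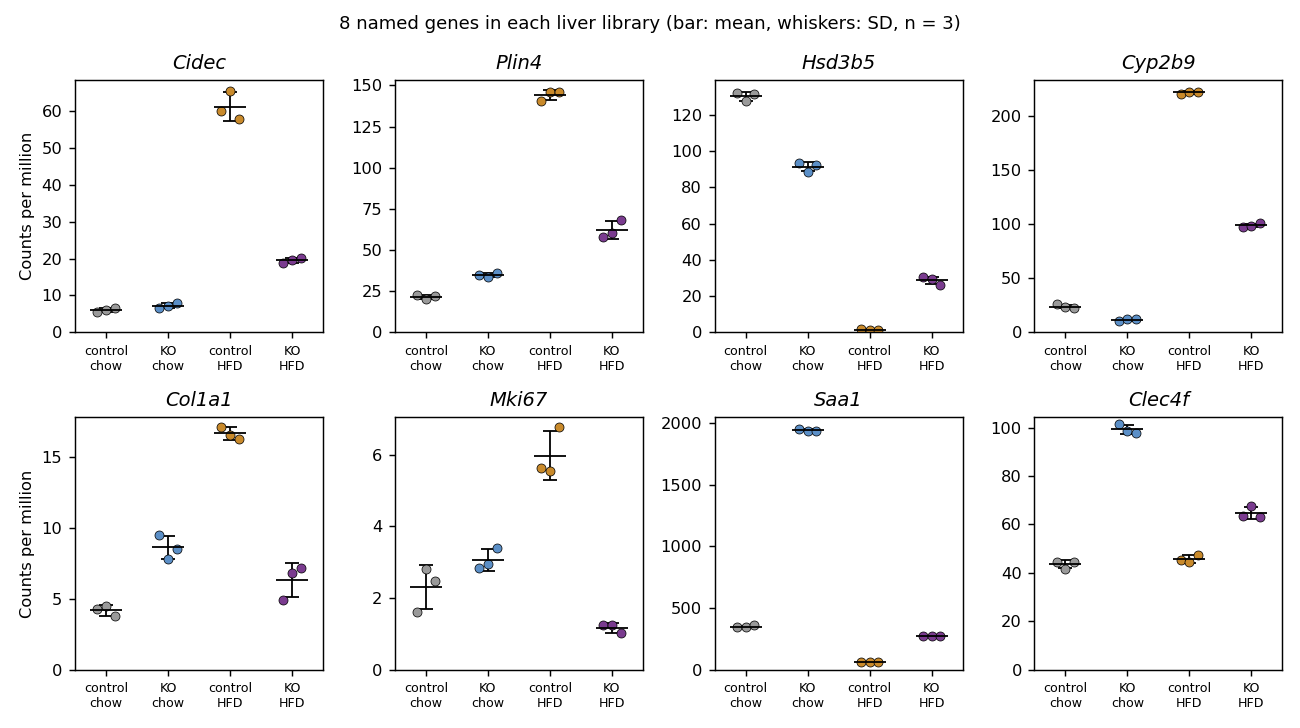
Depth-scaled counts (CPM, vertical axes, linear, from 0) of 8 named genes in each of the 12 libraries by group; points are libraries, bars the mean of 3 and whiskers the SD. Cidec, Plin4, Cyp2b9 and Col1a1 lie highest in controls on HFD, Saa1 and Clec4f in KO livers on chow, where Saa1 reaches 1943 CPM.

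**Figure D3:**
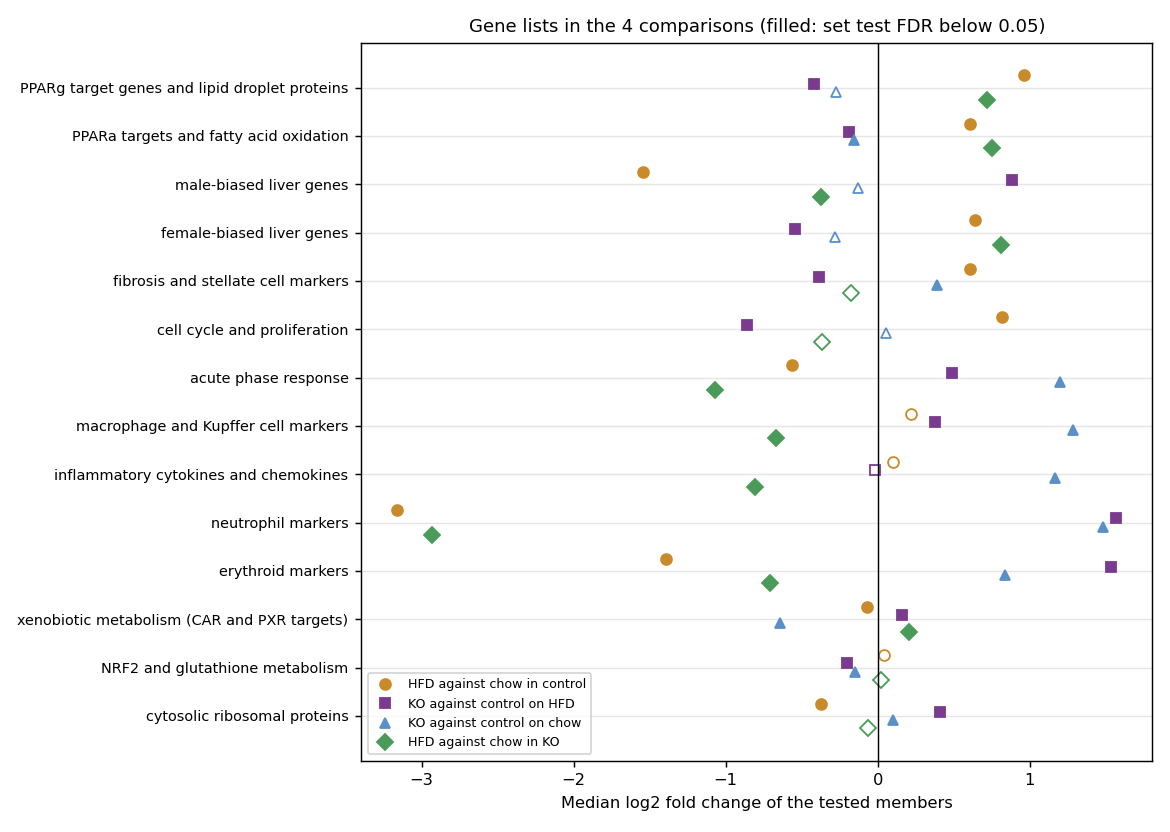
Median log2 fold change (horizontal axis) of the tested members of 14 gene lists in 4 comparisons, given by colour and marker; filled markers passed the set test with a preset correlation, and medians are of fitted values. The male-biased list lies at -1.54 for HFD in controls and at 0.89 for KO against control on HFD.

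Diet and knockout effects were next compared gene by gene in livers on HFD. Of the 5571 genes that differed by diet in controls, 2595 differed the opposite way and 450 the same way in KO livers on HFD, where independent lists, which leave out the shared controls, would give 902 of each. At 1.5-fold or more in both comparisons, 535 genes went opposite ways and 48 the same way. Of 939 genes higher on HFD by that fold, 463 were lower in KO livers, and of 854 genes lower on HFD, 348 were higher. Such counts do not require that the diet effect itself was smaller in KO livers. Pparg is counted, at 0.34 with the diet in controls and -0.60 in KO livers on HFD, though its interaction did not pass. How many of the 2595 genes passed the interaction was not counted. The 2 comparisons share the 3 control libraries on HFD, which alone opposes the signs. Across all tested genes 68.5% had opposite signs and the fold changes correlated with r = -0.49. In 100 simulated sets of unchanged groups sharing those libraries these were 66.2% and r = -0.48, which is nearly as much. Neither measure reflects how large the fold changes are. No simulated set had a gene past the threshold in opposite directions in both comparisons (highest 0), against 2595 here. The simulated groups held no diet or knockout effect, so hardly any gene could pass in either comparison. That 0 thus does not show how many of the 2595 come from sharing the controls. The covariance was -0.135 against -0.0224 in the simulation, a difference of -0.113. The simulation holds only the spread between these libraries, so it leaves out any deviation that the 3 controls share. The 3 controls could not be split into sets of at least 2 libraries, so part of the excess may still come from such a deviation.

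**Figure D4:**
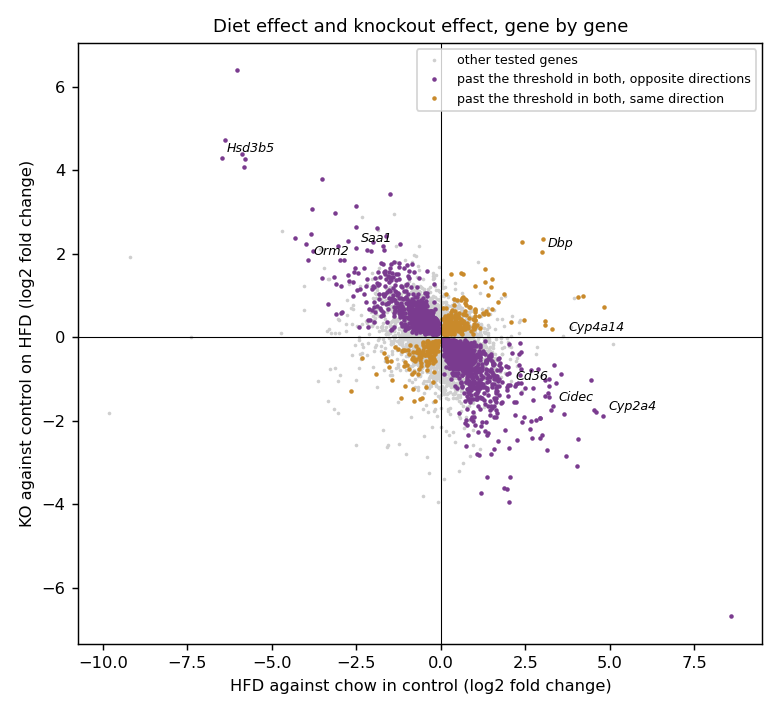
Log2 fold change of HFD against chow in controls (horizontal axis) and of KO against control on HFD (vertical axis) for the 14778 tested genes, one point each, with genes past the threshold in both comparisons in colour. Of these, 2595 lie in the quadrants of opposite sign, with Hsd3b5 at the upper left and Cidec at the lower right, and 450 in those of the same sign.

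On chow the comparison of KO with control livers asks what the knockout did without the diet. Acute phase genes were among the largest rises. Lcn2, an acute phase and neutrophil gene, was at 442 ± 11.9 CPM in KO livers against 38.4 ± 1.65 in controls (log2 fold change 3.52, SE 0.041), Saa2 at 2035 ± 16.0 against 260 ± 4.77 CPM (2.97, SE 0.025), and Saa1 at 1943 ± 9.34 against 350 ± 8.47 CPM (2.47, SE 0.024). The muscarinic receptor gene Chrm3 rose by 6.33 from 0.0679 CPM (4 counts in 3 libraries), the inositol synthase gene Isyna1 by 2.57, Ciart by 3.61 and Elf3 by 2.65. Lower in KO livers were Mme, which encodes neprilysin, at -3.01, Socs2, a feedback inhibitor of growth hormone signalling, at -2.22, Onecut1, a hepatocyte transcription factor gene, at -2.11, Gsta2 at -2.00 and Cyp2b10 at -2.00. Past the threshold were 4604 genes, 2341 higher and 2263 lower. At 1.5-fold or more there were 1448, of which 985 were higher and 463 lower.

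Acute phase genes were higher for 24 of 25 members and lower for 1 in KO livers on chow (24 and 1 adjusted over the list alone), with a median of 1.20 and Hp at 1.36. Macrophage and Kupffer cell markers were higher for 27 of 29 (28 adjusted over the list alone), with Cd5l at 1.48, Csf1r at 1.29, Mpeg1 at 1.22 and Clec4f at 99.2 ± 1.83 against 43.6 ± 1.68 CPM. Cytokine and chemokine genes were higher for 15 of 20 (16 adjusted over the list alone), Cxcl1 by 2.40, the adhesion molecule genes Vcam1 and Icam1 by 2.04 and 1.01, and neutrophil markers for 12 of 13 (12 adjusted over the list alone), S100a9 by 1.60. Erythroid markers were higher for 4 of 8 and lower for 2 (5 and 2 adjusted over the list alone), Hbb-bs by 0.93, with adjusted p = 0.104 with an estimated correlation. Fibrosis markers were higher for 18 of 29 (19 adjusted over the list alone), Col3a1 by 0.63, and endoplasmic reticulum stress genes for 18 of 26, with 2 lower (21 and 3 adjusted over the list alone), Asns by 1.24 and Herpud1 by 0.81. Sinusoidal endothelial markers were higher for 12 of 20 (13 adjusted over the list alone), Cdh5 by 0.61. None of the members of the macrophage, cytokine, neutrophil, fibrosis and endothelial lists was lower.

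Several lists of hepatocyte metabolism were lower in KO livers on chow. Cholesterol synthesis genes went the other way: 16 of 25 members were higher and 6 lower (17 and 6 adjusted over the list alone). Their set test had adjusted p = 0.072 with an estimated correlation. Hepatocyte identity genes were split, with 11 of 22 higher and 11 lower (11 and 11 adjusted over the list alone), though their set test pointed up (adjusted p = 0.0128). Of 24 xenobiotic metabolism genes 16 were lower and 5 higher in KO livers (16 and 5 adjusted over the list alone), with a median of -0.64, Cyp2c54 at -1.24 and Cyp3a11 at -0.97. Bile acid genes were lower for 16 of 24 and higher for 2 (16 and 2 adjusted over the list alone), including Cyp8b1, the sterol 12-hydroxylase gene that sets the make-up of bile acids, at -1.04. PPARa targets and oxidation genes were lower for 28 of 38 and higher for 5 (29 and 6 adjusted over the list alone), Cyp4a10 at -1.32 and Ehhadh at -0.85, while Cyp4a14 rose by 1.23. Nuclear genes of oxidative phosphorylation were lower for 22 of 31 and higher for 1 (23 and 1 adjusted over the list alone), by a median of -0.19; the higher member was Ucp2, an uncoupling protein gene, at 1.32. De novo lipogenesis genes were lower for 14 of 25 and higher for 4 (15 and 4 adjusted over the list alone), with adjusted p = 0.072 with an estimated correlation. The PPARg and lipid droplet list had 8 of 18 members lower and 4 higher (9 and 5 adjusted over the list alone) and did not pass its set test (adjusted p = 0.075); Plin4 rose by 0.70 and Plin2 fell by 0.25.

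In KO livers the diet comparison asks what HFD did once Pld1 was low. Oxidation genes rose again, and acute phase, macrophage and cytokine genes were lower. Cyp4a14 rose from 234 ± 5.45 to 1243 ± 15.8 CPM (log2 fold change 2.41, SE 0.024), Cyp4a10 by 2.25, Cyp2b9 by 3.09, Rgs16 by 2.74 and the protease gene Ctse by 2.47. Saa2 fell from 2035 ± 16.0 to 129 ± 3.07 CPM (-3.98, SE 0.026), and the chemokine gene Cxcl14 was at -4.98, Igdcc4 at -6.80, Elf3 at -4.65 and Isyna1 at -3.83. Moxd1 had no count in KO livers on HFD and was at least 886-fold lower there, against a floor of 3 counts over the group. Past the threshold were 5412 genes, 2732 higher and 2680 lower. At 1.5-fold or more there were 1685, of which 512 were higher and 1173 lower.

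PPARa targets and oxidation genes were higher for 37 of 38 members (37 adjusted over the list alone), with none lower, a median of 0.75 and Aldh3a2 at 1.27. PPARg targets and lipid droplet proteins were higher for 14 of 18 and lower for 1 (14 and 1 adjusted over the list alone), with Cidec at 1.43 and Plin2 at 0.68; the lower member was Lpl, lipoprotein lipase, at -2.04. Lipoprotein genes were higher for 18 of 20 and lower for 1 (18 and 1 adjusted over the list alone), Apoe by 0.41, and oxidative phosphorylation genes for 28 of 31, with 1 lower (28 and 1 adjusted over the list alone). Acute phase genes were lower for 23 of 25 and higher for 1 (23 and 1 adjusted over the list alone), macrophage markers for 24 of 29 (26 adjusted over the list alone), with Cd14 at -2.23, cytokine genes for 14 of 20, with 1 higher (14 and 1 adjusted over the list alone), and neutrophil markers for 12 of 13 (13 adjusted over the list alone). Male-biased genes were lower for 19 of 26 and higher for 2 (19 and 2 adjusted over the list alone), with a median of -0.37 and Selenbp2 at -2.00. Each of these set tests passed with an estimated correlation too.

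The effects of HFD in the 2 genotypes share no library. They correlated across all tested genes with r = 0.45 and Spearman's rho = 0.26, genes not being independent replicates, and of the 3081 genes past the threshold in both 1232 were higher and 1115 lower on HFD in both genotypes, where independent lists would give 513 and 507, and 734 went opposite ways, where they would give 1020. The effects of the knockout on the 2 diets correlated less, with r = 0.15 and rho = 0.13; 2211 genes passed in both, of which 1403 went the same way and 808 opposite ways. Independent lists would give 392 higher in both, where 720 were found, 354 lower in both, where 683 were found, and 745 in opposite directions, where 808 were found. Whether the knockout effect differed between diets was tested as an interaction. It was past the threshold for 4411 genes, 2241 with a more positive knockout effect on HFD and 2170 with a more negative one. At 1.5-fold or more there were 1622, of which 540 were more positive and 1082 more negative. Cd36 was among them (log2 difference -1.02), though not with the variation of every gene set to 20% (adjusted p = 0.0647). Also among them were Cidec (-1.90), Plin4 (-1.91), Col1a1 (-2.44) and Hsd3b5 (4.81). Pld1 (-0.05) and Pparg (-0.08) did not pass. The interaction went with transcript length across genes (Spearman's rho -0.231, genes not being independent), much as KO against control on HFD did. With each library's trend on length and GC content removed, 4050 genes passed, 3583 of them among the 4411.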

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

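The tests on the spread between libraries and on the acute phase genes were chosen after the results were seen, and the removal of the trend on length and GC was added after seeing the data. The genes and lists given first differed between the diets by the interaction test, with values as the knockout effect on HFD minus that on chow.

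The interaction was past the threshold for 4411 genes. Among the genes with the largest log2 difference, Hsd3b5 was at 4.81, the pseudogene Serpina4-ps1 at 3.63, the neutrophil gene Ngp at 2.91, the vomeronasal receptor gene Vmn1r90 at 2.83 and Socs2 at 2.79. On the lower side were Chrm3 at -6.49, Igdcc4 at -3.81, Ly6d at -3.64 and Ccdc120 at -3.49, and Cd36 was at -1.02. Chrm3 rested on 0.0679 CPM in controls on chow.

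Lists whose knockout effect was more negative on HFD than on chow were, by median log2 difference, cell cycle genes at -1.28, cytokines and chemokines at -1.18, macrophage markers at -0.83, fibrosis markers at -0.70, the acute phase at -0.52, cholangiocyte markers at -0.36, PPARg targets and lipid droplet proteins at -0.28, endoplasmic reticulum stress at -0.23 and endothelial markers at -0.23. More positive on HFD were male-biased genes at 1.06, erythroid markers at 0.73, bile acid genes at 0.45, xenobiotic metabolism at 0.36, periportal genes at 0.34, lipoprotein genes at 0.32, ribosomal protein genes at 0.31, oxidative phosphorylation at 0.30, pericentral genes at 0.27, hepatocyte identity genes at 0.26, mitochondrially encoded genes at 0.26 and de novo lipogenesis at 0.21. With an estimated correlation the last 2 had adjusted p = 0.169 and 0.153. After removal of the trend on length and GC, the mitochondrially encoded list no longer passed (adjusted p = 0.811, median -0.0097). Other medians shrank while their lists still passed: periportal genes to 0.23, lipoprotein genes to 0.19, ribosomal protein genes to 0.17, hepatocyte identity genes to 0.17 and oxidative phosphorylation to 0.15. The interaction of Cd36 did not pass with the variation of every gene set to 20% (adjusted p = 0.0647) or 40% (adjusted p = 1).

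The number of genes past the threshold in the interaction was highest for the real groups among 100 groupings of the 12 libraries, with 4411 against 777 in the next, and 1 of the 100 gave as many. The other groupings mix libraries of different real groups, which widens the spread within them, so this shows that the 12 libraries are not exchangeable and does not test the interaction apart from the effects of diet and genotype. For the number of lists, 7 of 100 groupings, the real one included, gave at least the real 21, and the highest other gave 23. The same mixing of real groups applies here, so this share neither excludes chance for that count nor shows it.

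Libraries of a group differed by little, with a common coefficient of variation of 3.95%. The files are not copies of a single library, since the lowest median chi-square between libraries of a group was 1.59 times its expectation. Genes of the acute phase, clock and immediate early lists, which tend to vary between mice, had a median spread within groups of 0.992 times that of genes of like abundance (bootstrap interval 0.862 to 1.11, 45 genes). This is what a single RNA source per group would give, and a candidate explanation is that the 3 libraries of a group came from shared or pooled RNA. Animals that were unusually alike remain open, and if the source was shared the tests say nothing of the spread between animals.

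Acute phase and macrophage genes were higher in KO livers on chow than in controls. More blood in the KO livers, as far as globin genes measure it, does not account for the rise of 15 of 25 acute phase members. These rose by more than the globin gene that rose the most (log2 fold change 0.94). The other members did not. Globin genes need not follow white blood cells, and neutrophil markers rose on chow by a median of 1.48. The globin comparison did not cover the macrophage genes, for which blood remains open. A lower share of hepatocytes would raise markers of the other cells alike, but the macrophage median lay 1.02 above the endothelial one (bootstrap interval over list members, not livers, 0.88 to 1.14). This in turn covers the macrophage genes only, and of their rise only the excess over the endothelial markers. The endothelial, cholangiocyte and fibrosis lists had positive medians on chow too (0.27, 0.27 and 0.39). Hepatocyte identity genes were split, 11 higher and 11 lower. A lower share of hepatocytes could thus account for part of the macrophage rise, which was not tested. An effect of the knockout on the acute phase genes remains open: 22 of the 25 members were higher in KO livers on both diets. A cause confined to the KO livers on chow, such as an illness in a shared source, cannot account for the rise on HFD (median 0.49), but it could add to the larger rise on chow and was not tested. The rise on HFD is measured against controls on HFD, in which 16 of 25 members were lower and 6 higher than in controls on chow (median -0.56). A low level in those controls could thus give such a rise too, and was not tested.

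Short-transcript genes were higher in KO livers on HFD, ribosomal protein genes among them at a median of 0.41. After removal of each library's trend on length and GC the median was 0.28, so the trend could account for part of this shift. The removal used the longest annotated transcript of each gene, which need not be the expressed one, and may take out too little. Whether such a trend accounts for the rest thus cannot be told. Of the 22 lists past the set test in that comparison, 21 passed in the same direction after the removal; the lipoprotein list did not (adjusted p = 0.37), and 3 other lists passed newly, making 24. A difference in RNA quality between groups remains open as untested, and so does a biological change in ribosomal protein genes.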

How the results depend on the processing

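The settings with a fixed coefficient of variation and with the trend on length and GC removed were chosen after seeing the data. Counts of genes past the threshold stayed within 1.5 times under each scaling, filter, test and left-out library: without single libraries they ran from 4139 to 4828 for KO against control on HFD, 4907 to 5657 for HFD in controls, 3977 to 4676 for KO on chow, 4756 to 5462 for HFD in KO and 3934 to 4184 for the interaction. Fold size and assumed variation decided them. A fold of at least 1.5 left 1063, 1793, 1448, 1685 and 1622 genes in the same order, a coefficient of variation of 20% left 534, 1194, 931, 1102 and 510, and one of 40% left 72, 259, 90, 216 and 22; the fall follows from the settings. Genes with opposite diet and knockout effects on HFD numbered 2232 to 2601 without single libraries, 276 at 20% and 40 at 40%. Shared knockout effects fell from 1403 to 101 and 12 genes, and shared diet effects from 2347 to 426 and 86. Pld1 kept its direction throughout (-1.54 to -1.28 on HFD and -1.51 to -1.29 on chow without single libraries), but at 40% it did not pass (-1.45, adjusted p = 0.315, and -1.39, adjusted p = 0.276).

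With an estimated correlation 15 lists instead of 23 passed for KO on chow. Replicate numbers did not pair the libraries: same-numbered libraries had deviations correlating at -0.131 to 0.157, and 4 of 12 libraries correlated best with their own number. The replicate block gave 4741, 5515, 4544, 5357 and 4331 genes in the order above.

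Most named genes were picked in these same data for a large fold or a small p, which favours keeping their calls. Over 484 named gene results and 20 planned settings, 9565 values kept direction and side of the threshold, 10 no longer passed and 4 changed sign. The sign changes were in the interaction of Pld1, which did not pass in any of them and ran from -0.16 to 0.11 without single libraries: 0.045 without control_chow replicate 3, 0.0041 without control_HFD replicate 1, 0.066 without KO_chow replicate 3 and 0.11 without KO_HFD replicate 2. With the length and GC trend removed it was 0.0086, and the interaction of mt-Nd2 went from 0.26 to -0.0097; the cause was not tested beyond that removal. Over the settings added after seeing the data, 915 named gene values kept direction and side of the threshold, 535 no longer passed and 2 changed sign. Depth and spread limit small changes: in simulated data for KO against control on HFD, 36% of genes with the smallest simulated fold were recovered.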

Other observations

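The removal of the trend on length and GC was added after seeing the data. Levels of some clock genes differed widely between the groups. Dbp, a clock output gene, was at 0.858 ± 0.301 CPM in controls on chow, 4.89 ± 0.214 in KO livers on chow, 6.89 ± 0.521 in controls on HFD and 28.4 ± 2.16 in KO livers on HFD, and Ciart, a clock repressor gene, at 0.604 ± 0.146, 7.39 ± 0.829, 3.16 ± 0.556 and 15.6 ± 0.985 CPM. The clock list had 11 of 21 members higher and 7 lower on HFD in controls (11 and 7 adjusted over the list alone, adjusted p = 0.0674 with an estimated correlation) and 11 higher and 3 lower in KO livers on chow (11 and 4 adjusted over the list alone, adjusted p = 0.0207 with an estimated correlation). Collection times are not in the labels.

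Genes of hepatocyte identity were higher for 19 of 22 members and lower for 1 in KO livers on HFD (19 and 1 adjusted over the list alone), with Tat, a tyrosine-degrading enzyme gene, at 0.93, Apoa1 at 0.68 and Cps1, the first enzyme of the urea cycle, at 0.59. In controls on HFD 13 of them were lower and 3 higher (14 and 4 adjusted over the list alone), Cps1 by -0.89. Cholangiocyte markers were lower for 9 of 13 members and higher for 1 on HFD in KO livers (10 and 1 adjusted over the list alone), with Spp1, which encodes osteopontin, at -2.72 and Krt23 at 2.36.

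For KO against control on HFD the other lists were as follows. Gluconeogenesis genes were higher for 9 of 21 members and lower for 5 (9 and 6 adjusted over the list alone), with Pck1, the cytosolic enzyme that commits carbon to glucose synthesis, at 0.44. Lipoprotein genes were higher for 13 of 20 and lower for 4 (13 and 4 adjusted over the list alone), with Apoa1 at 0.68 and Apoa4 at -1.73, but after removal of the trend on length and GC the median went from 0.17 to 0.038 and the list no longer passed (adjusted p = 0.37). Periportal genes were higher for 10 of 15 and lower for 2 (10 and 2 adjusted over the list alone, adjusted p = 0.0535 with an estimated correlation), with a median of 0.15 that was 0.087 after that removal, and immediate early genes for 8 of 25, with 4 lower (9 and 5 adjusted over the list alone, adjusted p = 0.0666 with an estimated correlation). In the pericentral list, with 5 of 16 higher and 7 lower (5 and 8 adjusted over the list alone), the set test and the mean of 0.14 pointed up and the median of -0.07 down. Set tests did not pass for fatty acid uptake (adjusted p = 0.092), triglyceride turnover (0.835), the phospholipase D family (0.835), cytokines (0.831), lymphocyte markers (0.111), endothelial markers (0.753), cholangiocyte markers (0.753), adipocyte markers (0.106), the interferon response (0.145), endoplasmic reticulum stress (0.635), oxidative phosphorylation (0.0776) and mitochondrially encoded genes (0.927). After removal of the trend on length and GC, the lists for fatty acid uptake (adjusted p = 0.0154), adipocyte markers (0.0324) and mitochondrially encoded genes (0.0433) passed, each as lower in KO livers. Sex chromosome genes and pancreatic acinar markers had 4 and 2 tested members, too few for a set test.

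For comparisons of 3 with 3 libraries only 10 splits exist, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. Fits of the 6 libraries alone called 4704, 5572, 4585 and 5271 genes for KO on HFD, HFD in controls, KO on chow and HFD in KO, and the highest other split called 0. For lists the real splits gave 22, 20, 24 and 22 and the highest others 10, 12, 12 and 18, and 1 of 10 splits again gave as many. Over the 36 other splits 4 to 18 lists passed, with a median of 10, though no gene did. The largest absolute median of such a list was 0.847, so a passed set test alone does not mark the real grouping. The other splits keep 2 of the 3 libraries of a group on one side, so they still hold part of the real difference. Among 100 groupings of the 12 libraries, only the real one gave as many genes with opposite diet and knockout effects on HFD. It gave 2595 against 757 in the next. It was also the only one with as many shared knockout effects, 1403 against 46, and shared diet effects, 2347 against 0. These groupings mix libraries of different real groups and so call few genes, which shows that the 12 libraries are not exchangeable and nothing more about these 3 counts.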
